A study of Mus musculus with 20 samples.

How the data were processed

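Liver RNA from 20 mouse samples was analysed, grouped by genotype, sex and exposure as their titles give them. Per the labels' protocols, total RNA was extracted from bulk liver with a Direct-zol kit that removes genomic DNA, samples with an RNA integrity number above 7 were sequenced, and BGI Americas made the libraries and ran them on its own platform. The series' design text gives the PFOA level as 8 µm, which was read here as micromolar. Per the submitters' processing notes, FastQC 0.11.5, cutadapt 1.15, STAR 2.5.3, featureCounts 1.6.1, R 4.1.0 and edgeR 3.36.0 were used, with the genome build GRCm39; the role of each, the annotation release and the strand setting are not given in the sources used here. The authors deposited 2 tables of whole-number counts per gene, with no normalization, 1 for each genotype. Both tables held the same 53599 gene symbols, of which 17159 had no count in any library and 0 named no gene, and all 20 columns were used. No coordinates are given, because the reference at hand was of another build.

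Near-identical genes, such as those of the Cyp4a, Cyp2b, Cyp2c, Cyp3a, Mup, Sult and Acot families, could have shared or lost reads in the authors' counting, so their single values are uncertain, as are those of overlapping and antisense genes. Replicates were compared before use. The chi-square per gene between libraries of a group ran from 7.94 to 46.4, where counting noise alone gives about 1, and their correlation of log2 CPM from 0.975 to 0.989, so no library was counted as a repeat of another.

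The counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors (0.895 to 1.08), the default filter on low counts by group and the robust quasi-likelihood test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The filter goes by the smallest group, which was 1 library in the KO and joint fits. A gene high in KO female vehicle replicate 1 alone could therefore be tested. PFOA in KO tested 15334 genes with that library and 13848 without it. The SE of a log2 fold change is its size divided by the square root of the test's F value. PFOA against vehicle and male against female were tested within each genotype's table in an additive model of exposure and sex. Effects within a sex and the PFOA by sex term came from a model with 4 groups, and all differences between genotypes from 1 model of the 20 libraries with the terms of each genotype. CPM values were computed here from the deposited counts and TMM factors. Interaction values are on the log2 scale and named by their order, such as KO minus hPPARa.

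Lists of liver pathways, receptor targets, sex-biased genes and cell type markers were fixed before the data were examined, as were the groups, the tests, the alternatives and the rule for named genes. A list needed 5 tested members. Lists were tested against the other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation; camera p-values were adjusted over the lists of a comparison. Each list's calls were counted among all genes tested and also adjusted over the list alone. The rule for named genes took, among genes past the threshold with a mean of at least 1 CPM and no predicted-gene symbol, the 8 highest and 8 lowest log2 fold changes, up to 4 members of each list with the smallest adjusted p, for interactions the 8 with the smallest adjusted p, and where no gene passed the 5 with the smallest unadjusted p. Ppara was always taken, and with PFOA also Cyp4a10, Cyp4a14, Ehhadh, Pdk4, Cyp2b10, Cyp3a11, Cyp7a1, Fasn and Cidec. Some genes that the rule takes are not reported here. From the others the text gives those whose call held in the alternatives, a narrowing made after the values were seen, and names the library or setting where another is given. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had log2 fold changes of −2.21 ± 0.66 with PFOA in hPPARa (adjusted p = 0.0484), a call lost without any single library except hPPARa male PFOA replicates 1 and 3 (adjusted p = 0.0742 to 0.131; −2.94 without replicate 3), without the filter on low counts (0.109) and with an equal weight for the sexes (0.0703), and −1.30 ± 0.64 in KO (adjusted p = 0.225).

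Against a group with no count a fold is a lower bound from a floor of 3 counts over the group. With 1 to 3 counts on a side the ratio is given with its exact 95% interval for counts, and floors and intervals cover counting error only. The expected overlap of 2 sets of calls is the product of their sizes over the genes tested in both. The permutation tests are exact and two-sided.

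Each test was first run on simulated counts with the real means, library sizes and spread, in which 200 genes were changed by 1.5, 2 or 4-fold. For PFOA in hPPARa it recovered 30.6%, 67.1% and 92.6% of the changes of these sizes, with 10 false calls among 139, and for PFOA in KO 31.0%, 65.7% and 88.9%. For PFOA by genotype it recovered 6.12%, 52.6% and 74.0%, and for PFOA by sex 0%, 16.7% and 66.2%. The share of calls that were false ran from 0% for sex by genotype to 10.6% for sex in KO, with 10.2% for PFOA by sex. The simulation drew each gene on its own and set no library apart. The alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, the replicate number as a block, leaving out each library in turn, a joint fit of the libraries, an equal weight for both sexes and a shared sex term. A further setting, without the 3 KO libraries that held transcripts of the other sex, was chosen after seeing the data.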

Results

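Liver RNA was sequenced from male and female mice that either lacked PPARα, the nuclear receptor that senses fatty acids and switches on their oxidation (knockout, KO), or expressed the human form of that receptor (hPPARa). From weaning, the mice drank water with 0.5% sucrose, either alone (vehicle) or with perfluorooctanoic acid (PFOA, a persistent fluorinated surfactant) at 8 µM, for 6 to 7 weeks. Their diet supplied 51.8% of its energy as carbohydrate, 33.5% as fat and 14.7% as protein. There were 20 libraries in 8 groups. On vehicle these were 3 hPPARa females, 2 hPPARa males, 1 KO female and 3 KO males, and on PFOA 2 hPPARa females and 3 libraries in each of the other groups. Total counts ran from 14973673 to 17953860 per library, and 19696 to 24481 genes had a count in a library. The labels do not say that the samples of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical.

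Ppara, the gene targeted in the knockout, had counts in every library, from 17.0 to 39.6 CPM (counts scaled to the library total) in the hPPARa livers and from 8.42 to 25.1 CPM in the KO livers. The hPPARa group means were 20.7 ± 4.13 CPM (SD, n = 3) in females and 24.9 ± 2.98 (n = 2) in males on vehicle, and 28.0 ± 1.28 (n = 2) and 31.0 ± 9.25 (n = 3) on PFOA. The KO group means were 20.1 ± 0.148 CPM (n = 3) in males and 22.2 CPM in the 1 female on vehicle, and 21.5 ± 3.42 (n = 3) in males and 14.9 ± 6.10 (n = 3) in females on PFOA. The part of the gene that the knockout removes is not given in the sources used here, so this row does not check the genotype labels. Xist, the transcript of the inactive X chromosome, averaged 471 to 708 CPM in the female groups and 1.40 to 11 CPM in the male groups. The Y-linked gene Ddx3y averaged 44.5 to 53.9 CPM in the male groups. In 3 KO libraries there were transcripts of the other sex. KO female PFOA replicate 2 had 4.07 CPM of Ddx3y and 4.67 CPM of Eif2s3y, above the rest of its group, and KO male PFOA replicate 2 had 30.8 CPM of Xist, above the rest of its group. KO female vehicle replicate 1, which is alone in its group, had 1.86 CPM of Ddx3y and 3.05 CPM of Eif2s3y.

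What PFOA changes in livers with the human receptor was asked in 5 PFOA and 5 vehicle hPPARa libraries, with sex as a term. The lists of peroxisomal fatty acid oxidation, lipid droplet and drug metabolism genes rose. Ehhadh, a peroxisomal β-oxidation enzyme, rose 15.5-fold (log2 fold change 3.96 ± 0.13 SE, adjusted p = 1.09e-09). Cyp2b10, the classical target of the xenobiotic receptor CAR, rose 510-fold (8.99 ± 0.59, adjusted p = 2.66e-05), and Mogat1, a monoacylglycerol acyltransferase, rose 215-fold (7.75 ± 0.27, adjusted p = 1.11e-09). Wif1, a secreted Wnt inhibitor, fell 39.7-fold (−5.31 ± 0.28, adjusted p = 9.22e-08), and Ntrk2, a neurotrophin receptor, fell 32.2-fold (−5.01 ± 0.41, adjusted p = 8.57e-05). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1847 genes were higher and 1406 lower of 14400 tested, of which 571 and 381 changed at least 2-fold. The sum of 3253 calls became 1905 without hPPARa female PFOA replicate 1 and 2070 without hPPARa female PFOA replicate 2.

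Of 25 tested members of the list of peroxisomal and PPARα-inducible oxidation genes, 21 rose and 0 fell (21 and 1 adjusted over the list alone), with a median log2 fold change of 1.87 and a camera adjusted p of 1.54e-21. Besides Ehhadh they included Acaa1b (log2 fold change 3.26 ± 0.15), a peroxisomal thiolase, and Aldh3a2 (2.66 ± 0.21), a fatty aldehyde dehydrogenase. The fatty acid ω-hydroxylase genes Cyp4a10 and Cyp4a14 rose by 7.23 ± 0.69 (adjusted p = 0.000268) and 8.36 ± 0.86 (adjusted p = 0.000457) on the log2 scale. For Cyp4a14 the log2 fold change was 7.65 without hPPARa male vehicle replicate 2, 8.96 without hPPARa female PFOA replicate 1 and 9.02 without hPPARa female PFOA replicate 2. In the mitochondrial fatty acid oxidation and ketogenesis list 18 of 22 members rose and 0 fell (18 and 0 adjusted over the list alone; camera adjusted p = 6.3e-14, adjusted p = 0.128 with an estimated correlation). Among them were Eci1 (1.81 ± 0.13), an enoyl-CoA isomerase, Hadhb (1.26 ± 0.12), a subunit of the trifunctional protein, and Slc25a20 (1.12 ± 0.09), the carnitine-acylcarnitine carrier. Lipid droplet and fatty acid uptake genes rose in 17 of 21 cases and fell in 0 (18 and 0 adjusted over the list alone; camera adjusted p = 1.08e-13). Fitm1, which promotes droplet formation, rose 54.3-fold, Cidec, a droplet fusion protein, 9.74-fold (3.28 ± 0.33) and Plin2, a droplet coat protein, 3.50-fold (1.81 ± 0.16). Pdk4, a kinase that restrains glucose oxidation and stands in the mitochondrial list, rose by 2.48 ± 0.41 on the log2 scale (adjusted p = 0.00345). Ppara stood at 0.37 ± 0.16 (adjusted p = 0.107), and passed the threshold without hPPARa male PFOA replicate 1 (0.47, adjusted p = 0.0112) or without the filter on low counts (adjusted p = 0.00981).

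Among targets of the xenobiotic receptors CAR and PXR, 28 of 40 members rose and 2 fell (28 and 2 adjusted over the list alone; camera adjusted p = 2.31e-17). Cyp2c55 rose 162-fold, Cyp3a11, the PXR target in mouse liver, 5.88-fold (2.56 ± 0.18, adjusted p = 1.00e-06), and Cyp2c54 by 1.78 ± 0.12 on the log2 scale. The peroxisomal, lipid droplet and CAR and PXR lists kept their call with an estimated correlation, with adjusted p of 0.0465, 0.03 and 0.0236, and no other list in these livers did. NRF2 oxidative stress genes rose in 9 of 20 cases and fell in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 3.92e-05, adjusted p = 0.155 with an estimated correlation). Abcc4, an efflux pump, rose by 3.09 ± 0.20, Nqo1, a quinone reductase, by 1.42 ± 0.12 and Srxn1, sulfiredoxin, by 1.19 ± 0.09. Cyp4a, Cyp2b, Cyp2c and Cyp3a genes each have near-identical copies among which the counting could have split reads, so the values of single members are uncertain.

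The fatty acid synthesis, lipoprotein and bile acid lists went in both directions. Of 25 fatty acid and triglyceride synthesis genes 11 rose and 4 fell (12 and 4 adjusted over the list alone; camera adjusted p = 0.0464, adjusted p = 0.45 with an estimated correlation). Fads2, a fatty acid desaturase, rose by 1.02 ± 0.14, while Pklr, liver pyruvate kinase, fell by 1.08 ± 0.17 on the log2 scale. Fasn, fatty acid synthase, rose by 0.52 ± 0.14 (adjusted p = 0.0147), a call lost without hPPARa male vehicle replicate 1 (0.38, adjusted p = 0.0524) and in the joint fit of all libraries (adjusted p = 0.245). In the lipoprotein list 4 of 27 members rose and 7 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.119); Apoc2, the lipoprotein lipase cofactor, fell by 1.76 ± 0.32 on the log2 scale and Ces1g, a carboxylesterase, rose by 1.45 ± 0.23. Of 23 bile acid and sterol efflux genes 5 rose and 4 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.829). Among them were Abcb4 (0.95 ± 0.10), the phosphatidylcholine exporter, and Baat (−0.71 ± 0.10), which conjugates bile acids. Among 26 cholesterol synthesis genes 5 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.187). Glucose and insulin response genes rose in 0 and fell in 10 of 21 cases (1 and 12 adjusted over the list alone; camera adjusted p = 0.00172, adjusted p = 0.231 with an estimated correlation). Khk, ketohexokinase, stood at −0.78 ± 0.10 and Igf1 at −1.03 ± 0.16.

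Cell cycle genes rose in 19 of 32 cases and fell in 2 (25 and 2 adjusted over the list alone; camera adjusted p = 9.86e-11, adjusted p = 0.155 with an estimated correlation). Top2a, a topoisomerase of dividing cells, rose 4.24-fold (2.08 ± 0.20, adjusted p = 1.14e-05) and Ccnb1, the mitotic cyclin, 19.5-fold. Complement and coagulation genes rose in 0 and fell in 14 of 33 cases (0 and 15 adjusted over the list alone; camera adjusted p = 0.000482, adjusted p = 0.466 with an estimated correlation). Among them were C9 (−1.44 ± 0.26), a pore component, and F11 (−1.10 ± 0.19), a clotting factor. Interferon response genes rose in 0 and fell in 9 of 24 cases (0 and 14 adjusted over the list alone; camera adjusted p = 6.04e-06, adjusted p = 0.45 with an estimated correlation). Among them were Ifit1 (−1.69 ± 0.28) and Psmb8 (−1.08 ± 0.15). Of 20 hepatocyte markers 0 rose and 12 fell (0 and 14 adjusted over the list alone; camera adjusted p = 1.22e-06, adjusted p = 0.155 with an estimated correlation). Ahsg stood at −1.09 ± 0.12 and Ttr, transthyretin, at −0.91 ± 0.12. Among markers of other liver cells, 0 of 19 Kupffer cell and macrophage genes rose and 6 fell (0 and 6 adjusted over the list alone; camera adjusted p = 0.0795), including the scavenger receptor Marco (−1.74 ± 0.33). Of 17 endothelial genes 6 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.0976), including Lyve1 (2.10 ± 0.23). Acute-phase genes rose in 0 and fell in 3 of 28 cases (0 and 1 adjusted over the list alone; camera adjusted p = 0.0214, adjusted p = 0.466 with an estimated correlation). Circadian genes rose in 1 and fell in 6 of 19 cases (4 and 9 adjusted over the list alone; camera adjusted p = 0.0211, adjusted p = 0.311 with an estimated correlation). Mitochondrially encoded genes, a sign of RNA handling, rose in 0 and fell in 2 of 7 cases (0 and 2 adjusted over the list alone; camera adjusted p = 0.0201, adjusted p = 0.556 with an estimated correlation). They held 12.9% of the counts in hPPARa male PFOA replicate 1 against 9.64% and 9.07% in the other males on PFOA.

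**Figure D1:**
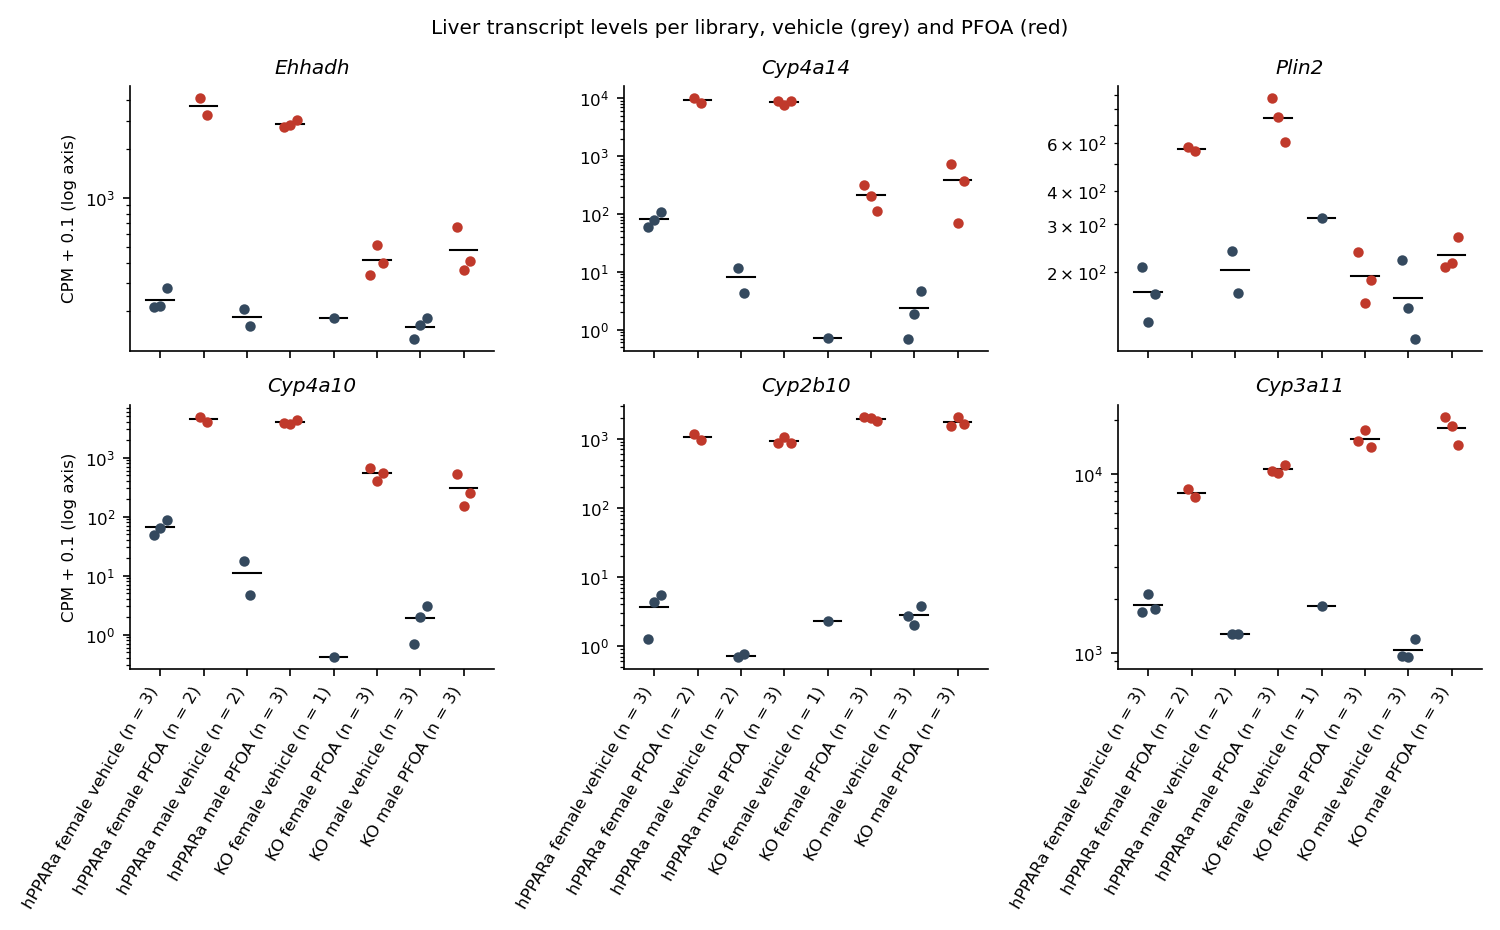
Level of 6 transcripts in each of the 20 libraries, in CPM with 0.1 added so that the log axis can show low values; a point is a library and a line the group mean. Ehhadh reached 2730 to 4140 CPM in the hPPARa PFOA libraries and 337 to 666 CPM in the KO PFOA libraries, while Cyp2b10 lay between 860 and 2070 CPM in all of them.

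Within hPPARa males, 3 PFOA and 2 vehicle libraries, 763 genes were higher and 418 lower, and within hPPARa females, 2 and 3 libraries, 1511 and 1133. Of the genes called, 539 were higher in both sexes and 259 lower in both, against 80.1 and 32.9 for independent lists, and 798 of the 803 called in both had the same sign. Ehhadh rose by 3.95 ± 0.20 in males and 3.97 ± 0.17 in females. Mitochondrially encoded genes fell in 7 of 7 cases in females and rose in 0 (0 and 7 adjusted over the list alone; median −0.78, camera adjusted p = 7.1e-05, adjusted p = 0.326 with an estimated correlation). In males they rose in 0 and fell in 0 (0 and 0 adjusted over the list alone; camera adjusted p = 0.726). Interferon genes fell in 12 of 24 cases in females and rose in 0 (0 and 19 adjusted over the list alone; camera adjusted p = 3.85e-08, adjusted p = 0.326 with an estimated correlation). In males 0 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.0152, adjusted p = 0.623 with an estimated correlation). The male total of 1181 calls became 468 without hPPARa male vehicle replicate 1 and 485 without hPPARa male vehicle replicate 2. The female total of 2644 became 796 (561 higher and 235 lower) without hPPARa female PFOA replicate 1, 808 (573 and 235) without hPPARa female PFOA replicate 2 and 1739 without hPPARa female vehicle replicate 1.

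Whether the response differs between the sexes was tested by the PFOA by sex term, which called 6 genes higher and 9 lower in males than in females, relative to vehicle. With DESeq2 there were 79 and 59, and without the filter on low counts 172 and 151. Cyp2c29, a xenobiotic-inducible P450, rose by 4.26 ± 0.18 in females (adjusted p = 4.31e-08), and its response was lower in males by a log2 difference of −2.47 ± 0.24 (adjusted p = 0.00086), as was that of Cyp2c67 (−2.18 ± 0.21, adjusted p = 0.00086). Of the female-biased liver genes 2 of 31 were higher and 0 lower by this term, with a median difference of 2.62 (12 and 0 adjusted over the list alone; camera adjusted p = 4.34e-14, adjusted p = 0.19 with an estimated correlation). In females 1 of these 31 rose and 12 fell with PFOA (2 and 16 adjusted over the list alone; camera adjusted p = 1.03e-05, adjusted p = 0.254 with an estimated correlation). In males 5 rose and 3 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.0241, adjusted p = 0.459 with an estimated correlation). Of the male-biased genes 1 of 29 was higher and 4 were lower in males (1 and 7 adjusted over the list alone; camera adjusted p = 0.000266, adjusted p = 0.33 with an estimated correlation). In females 6 were higher and 2 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.657). The PFOA by sex term called 0 of 7 mitochondrially encoded genes (6 and 0 adjusted over the list alone; camera adjusted p = 1.47e-05, adjusted p = 0.511 with an estimated correlation). It called 0 of 24 interferon genes (0 and 0 adjusted over the list alone; camera adjusted p = 2.55e-05, adjusted p = 0.511 with an estimated correlation). The count of 15 rested on single libraries. It became 4 without hPPARa female PFOA replicate 1 or replicate 2, 7 without hPPARa male vehicle replicate 2, 9 without hPPARa female vehicle replicate 1, 27 (16 higher and 11 lower) without hPPARa male PFOA replicate 1, 26 without hPPARa male PFOA replicate 2 and 26 (16 and 10) without hPPARa female vehicle replicate 3.

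What PFOA changes without PPARα was asked in 6 PFOA and 4 vehicle KO libraries. The CAR and PXR targets rose as a group, and the peroxisomal and mitochondrial oxidation genes rose too. Cyp2b10 rose 709-fold (log2 fold change 9.47 ± 0.24 SE, adjusted p = 4.74e-11), Cyp2c55 634-fold (9.31 ± 0.26, adjusted p = 2.73e-10) and Cyp3a11 13.4-fold (3.74 ± 0.22, adjusted p = 9.45e-07). S100a8, a subunit of the neutrophil protein calprotectin, rose 464-fold (8.86 ± 0.57, adjusted p = 5.85e-05). Sult2a1, a sulfotransferase for steroids and bile acids with close paralogs, fell 157-fold (−7.29 ± 0.41, adjusted p = 2.03e-07). This fall is that of the females, from 28.5 CPM in the 1 KO female vehicle library to a mean of 0.167 CPM on PFOA, since the KO males had 0.0225 and 0 CPM. With an equal weight for the sexes it stood at −4.69 (adjusted p = 0.0498). Ntrk2 fell by 6.27 ± 0.54 on the log2 scale. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1137 genes were higher and 976 lower of 15334 tested, of which 413 and 397 changed at least 2-fold. The sum of 2113 calls became 1401 without KO male PFOA replicate 2 and 1407, of which 854 were higher and 553 lower, without KO female vehicle replicate 1. It became 630, of which 440 were higher and 190 lower, without the 3 KO libraries with transcripts of the other sex.

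Of 40 CAR and PXR targets in KO livers 32 rose and 1 fell (33 and 1 adjusted over the list alone; camera adjusted p = 3e-31). Ces2a, a carboxylesterase, stood at 2.92 ± 0.14 and Cyp2c50 at 2.15 ± 0.11. Of 25 peroxisomal and PPARα-inducible genes 19 rose and 0 fell (19 and 1 adjusted over the list alone; median log2 fold change 0.98, camera adjusted p = 1.46e-12). Acaa1b rose 5.15-fold (2.37 ± 0.21), Ehhadh 2.71-fold (1.44 ± 0.20, adjusted p = 0.000827), and Eci2, an enoyl-CoA isomerase, by 1.16 ± 0.13 on the log2 scale. Cyp4a10 rose by 8.06 ± 0.81 (adjusted p = 0.000819), which became 9.06 with an equal weight for the sexes, 8.73 without KO male vehicle replicate 3 and 7.39 without KO female vehicle replicate 1. Cyp4a14 rose by 7.60 ± 1.01 (adjusted p = 0.00314), which became 8.36 without KO male vehicle replicate 3 and 7.01 without KO male PFOA replicate 1. Cyp4a10 was at 0.31 to 2.97 CPM in the KO vehicle libraries and at 149 to 678 CPM in the KO PFOA libraries, against 3730 to 4910 CPM in the hPPARa PFOA libraries. Mitochondrial oxidation genes rose in 11 of 23 cases and fell in 0 (13 and 2 adjusted over the list alone; camera adjusted p = 2.29e-06). Among them were Eci1 (1.47 ± 0.12), Slc25a20 (1.28 ± 0.11) and Decr1 (0.84 ± 0.09), a dienoyl-CoA reductase. These 3 lists kept their call with an estimated correlation (adjusted p = 0.0297 for the CAR and PXR list, 0.0297 for the peroxisomal list and 0.0396 for the mitochondrial list), and no other list in KO livers did.

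Lipid droplet genes rose in 8 of 21 cases and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00111, adjusted p = 0.448 with an estimated correlation). Lpl, lipoprotein lipase, stood at 1.86 ± 0.26, Pparg, the adipogenic receptor, at 0.84 ± 0.12 and Fitm2 at 0.89 ± 0.11. Cidec stood at 0.96 ± 0.37 (adjusted p = 0.117), and passed without KO female vehicle replicate 1 (1.68, adjusted p = 0.00607). It also passed without the 3 KO libraries with transcripts of the other sex (1.84, adjusted p = 0.0126) and without the filter on low counts (adjusted p = 0.000562). Pdk4 stood at −0.44 ± 0.43 (adjusted p = 0.542) and Fasn at −0.17 ± 0.40, neither past the threshold. NRF2 genes rose in 11 of 22 cases and fell in 2 (12 and 3 adjusted over the list alone; camera adjusted p = 0.000109, adjusted p = 0.134 with an estimated correlation). Among them were Srxn1 (1.31 ± 0.19) and Nqo1 (1.07 ± 0.15). Among cholesterol synthesis genes 3 of 26 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.0257, adjusted p = 0.748 with an estimated correlation). Tm7sf2, a sterol reductase, stood at 1.07 ± 0.15. Cell cycle genes rose in 11 of 32 cases and fell in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 0.000118, adjusted p = 0.496 with an estimated correlation). Among them were Mki67 (2.0 ± 0.29), the Ki-67 antigen, and Top2a (1.84 ± 0.27). Orm2, an acute-phase protein, rose by 1.96 ± 0.16 and C9 fell by 1.54 ± 0.18 on the log2 scale.

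Hepatocyte markers in KO livers rose in 0 and fell in 7 of 20 cases (0 and 12 adjusted over the list alone; camera adjusted p = 0.000109, adjusted p = 0.23 with an estimated correlation). Trf, transferrin, stood at −0.75 ± 0.13 and Ahsg at −0.72 ± 0.12. Kupffer cell and macrophage markers rose in 4 of 20 cases and fell in 0 (6 and 0 adjusted over the list alone; camera adjusted p = 0.00498, adjusted p = 0.588 with an estimated correlation). Among them were Adgre1 (0.98 ± 0.17), the F4/80 antigen, and Cd163 (0.74 ± 0.16). Cholangiocyte markers fell in 7 of 13 cases and rose in 0 (0 and 10 adjusted over the list alone; camera adjusted p = 0.00031, adjusted p = 0.466 with an estimated correlation), with a median log2 fold change of −1.50. Of the vehicle libraries, KO female vehicle replicate 1 held 60.8 CPM of the bile duct keratin Krt19, 849 CPM of the mucosal protein Dmbt1 and 13.4 CPM of the epithelial adhesion molecule Epcam. KO male vehicle replicate 3 held 3.60, 27.9 and 3.16 CPM of them. Krt19 had a log2 fold change of −4.93 ± 1.03 (adjusted p = 0.0193). It was −1.76 (adjusted p = 0.0776) without KO female vehicle replicate 1 and −1.63 (adjusted p = 0.234) without the 3 KO libraries with transcripts of the other sex. With the replicate number as a block it was −4.55 (adjusted p = 0.0814 by edgeR's quasi-likelihood test), and with DESeq2 −4.05. It was −4.66 (adjusted p = 0.0556) without KO female PFOA replicate 2 and −5.66 without KO male PFOA replicate 3. In the KO males alone 0 of the 13 rose and 0 fell (0 and 0 adjusted over the list alone; median −0.68, camera adjusted p = 0.0203, adjusted p = 0.495 with an estimated correlation). In the KO females 0 rose and 5 fell against that 1 vehicle library (0 and 10 adjusted over the list alone; camera adjusted p = 2.62e-07, adjusted p = 0.223 with an estimated correlation). Stellate cell and fibroblast markers rose in 0 and fell in 4 of 22 cases (0 and 4 adjusted over the list alone; camera adjusted p = 0.0123, adjusted p = 0.713 with an estimated correlation). Acta2, among them, was at 41 CPM in KO female vehicle replicate 1 and 34.9 CPM in KO male vehicle replicate 3, against 1.29 to 6.90 CPM in the other KO libraries. Mitochondrially encoded genes rose in 0 and fell in 2 of 7 cases (0 and 5 adjusted over the list alone; camera adjusted p = 0.0111, adjusted p = 0.564 with an estimated correlation).

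In KO males, 3 against 3 libraries, 864 genes were higher and 531 lower, and in KO females, 3 libraries against 1, 358 and 456. DESeq2 gave 558 and 415 in KO females. Cyp2b10 rose by 9.32 ± 0.25 in males (adjusted p = 8.2e-10) and 9.80 ± 0.44 in females (adjusted p = 3.35e-07). Of the male-biased liver genes 2 of 30 rose and 11 fell in KO males (2 and 16 adjusted over the list alone; camera adjusted p = 3.8e-05, adjusted p = 0.24 with an estimated correlation). Cyp7b1, a male-biased oxysterol hydroxylase, fell by 1.88 ± 0.20 in KO males. The female values rest on 1 vehicle library, which also held epithelial and Y-linked transcripts. Their SE and p borrow the spread between libraries of the other KO groups. The difference between the sexes within KO was not tested. The male total of 1395 calls became 635 without KO male PFOA replicate 2, 706 without KO male PFOA replicate 3, 728 without KO male vehicle replicate 1 and 929 without KO male PFOA replicate 1.

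Whether the response depends on the receptor was tested as the difference of the PFOA effects, KO minus hPPARa, in all 20 libraries. The peroxisomal, mitochondrial and lipid droplet genes responded less in KO livers, and the CAR and PXR targets more. The response of Ehhadh was lower in KO livers by a log2 difference of −2.52 ± 0.23 (5.73-fold, adjusted p = 2.11e-06). Those of Hsd17b11, a lipid droplet dehydrogenase, were lower by −1.78 ± 0.15 (adjusted p = 1.81e-06), Acot8, a peroxisomal thioesterase, by −0.92 ± 0.13 (adjusted p = 0.00199), Ephx2, the soluble epoxide hydrolase, by −1.14 ± 0.18 (adjusted p = 0.00336) and Hadhb by −0.95 ± 0.17 (adjusted p = 0.00835). The glutathione transferases Gstt3 and Gstm2 responded more in KO livers, by 1.66 ± 0.26 (adjusted p = 0.0043) and 1.94 ± 0.31 (adjusted p = 0.00563). Lower in response as well were Chrna2, a nicotinic receptor subunit (−3.26 ± 0.39, adjusted p = 0.000289), Bhlhb9 (−3.29 ± 0.45, adjusted p = 0.00132) and Acsf3, a malonyl-CoA synthetase (−0.70 ± 0.11, adjusted p = 0.00336). Of 15811 genes 70 were higher and 115 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The sum of 185 became 67 without hPPARa female PFOA replicate 1, 85 without hPPARa female PFOA replicate 2, and 90 without KO male PFOA replicate 2. It became 81, of which 39 were higher and 42 lower, without KO female vehicle replicate 1. Without the 3 KO libraries with transcripts of the other sex it became 39, of which 23 were higher and 16 lower, so the excess of lower calls was lost.

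By list, the difference was 0 higher and 7 lower of 25 for peroxisomal genes (0 and 13 adjusted over the list alone; camera adjusted p = 7.1e-15). It was 0 and 4 of 23 for mitochondrial oxidation (0 and 11 adjusted over the list alone; camera adjusted p = 2e-10), 0 and 4 of 21 for lipid droplets (0 and 12 adjusted over the list alone; camera adjusted p = 1.44e-12). It was 7 and 0 of 40 for CAR and PXR targets (17 and 0 adjusted over the list alone; camera adjusted p = 9.06e-10). All 4 kept their call with an estimated correlation, with adjusted p of 0.0229, 0.0481, 0.0229 and 0.0481, and the other lists did not. Kupffer cell markers passed camera on the higher side in KO livers with 0 of 20 members past the threshold (11 and 0 adjusted over the list alone; camera adjusted p = 3.97e-06, adjusted p = 0.278 with an estimated correlation). Interferon genes passed it with 0 of 24 (0 and 0 adjusted over the list alone, so no single member supports it; camera adjusted p = 1.45e-08, adjusted p = 0.335 with an estimated correlation). Cholangiocyte markers were lower in 1 of 13 cases and higher in 0 (0 and 8 adjusted over the list alone; camera adjusted p = 1.32e-05, adjusted p = 0.191 with an estimated correlation), beside the high values of KO female vehicle replicate 1. The response did not differ past the threshold for Cyp4a10 (0.83 ± 0.97, adjusted p = 0.765), Cyp4a14 (−0.76 ± 1.21, adjusted p = 0.835), Cyp2b10 (0.46 ± 0.57, adjusted p = 0.778) or Ppara (−0.51 ± 0.30, adjusted p = 0.468).

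Across the 14240 genes tested in both genotypes, 688 were higher with PFOA in both, of 1807 in hPPARa and 1090 in KO, against 138 for independent lists. Of the genes lower, 402 were shared, of 1391 and 838, against 81.9. Of the 1097 genes called in both, 1090 had the same sign. Genes called higher in hPPARa had a median log2 fold change of 0.64 there and 0.37 in KO, and 88.7% had the same sign; for those called lower the medians were −0.66 and −0.35 and the share 89.1%. Genes called higher in KO had medians of 0.69 there and 0.55 in hPPARa, and 92.8% had the same sign; for those called lower they were −0.69 and −0.50, and 92.8%. Each set was chosen by its calls in 1 genotype, and that choice alone favours larger values there. The smaller medians in the other genotype therefore do not measure dependence on the receptor. Over the 14240 genes the fold changes correlated with Pearson's r = 0.678 and Spearman's rho = 0.562, across genes, which are not independent replicates.

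**Figure D2:**
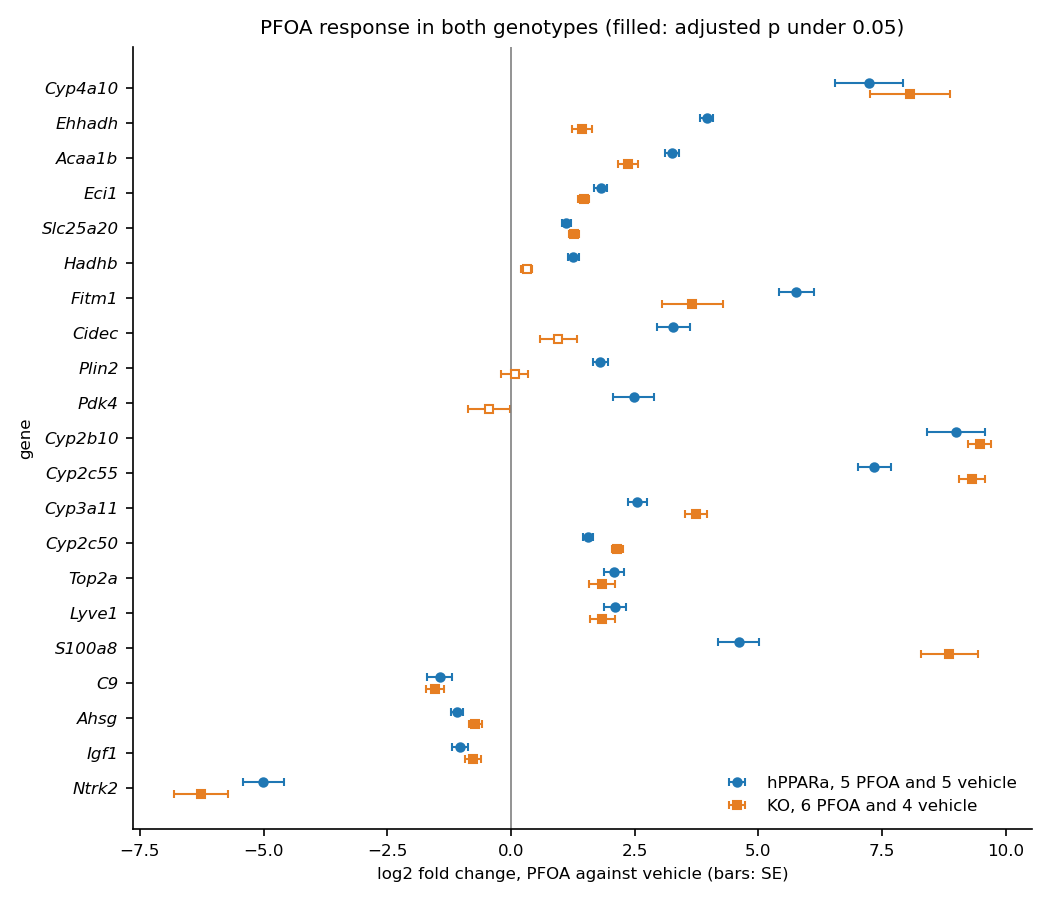
Log2 fold change with PFOA and its SE for 21 genes, in hPPARa (circles, 5 PFOA and 5 vehicle libraries) and KO (squares, 6 and 4 libraries), filled where the adjusted p is under 0.05. Ehhadh stands at 3.96 in hPPARa and 1.44 in KO, and Cyp3a11 at 2.56 and 3.74.

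How the genotypes differ on vehicle was asked in 4 KO and 5 hPPARa libraries. Peroxisomal oxidation genes were lower in KO livers as a list. Plin5, the droplet protein of oxidative tissues, was 12.2-fold lower (log2 difference −3.61 ± 0.24, adjusted p = 2.09e-08), Slc25a20 3.45-fold lower (−1.79 ± 0.11, adjusted p = 1.95e-09). Eci2 (−1.57 ± 0.13, adjusted p = 2.38e-07) and Slc25a34, a mitochondrial carrier (−2.37 ± 0.23, adjusted p = 3.08e-06), were lower as well. Cyp4a10 was lower by a log2 difference of −4.39 ± 0.79 (adjusted p = 0.00803), which became −5.07 without KO male vehicle replicate 3 and −3.74 without KO female vehicle replicate 1. Of 15811 genes 317 were higher and 279 lower in KO, and the sum of 596 became 351 without KO female vehicle replicate 1, with 248 genes in both sets of calls. Ppara differed by −0.19 ± 0.22 (adjusted p = 0.685).

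In the vehicle livers 0 of 25 peroxisomal genes were higher and 12 lower in KO (0 and 19 adjusted over the list alone; camera adjusted p = 4.38e-17, adjusted p = 0.0264 with an estimated correlation). Among them were Decr2 (−1.72 ± 0.20) and Acaa1b (−1.29 ± 0.19). For mitochondrial oxidation it was 0 and 9 of 23 (3 and 14 adjusted over the list alone; camera adjusted p = 2.57e-09, adjusted p = 0.113 with an estimated correlation). Among them was Cpt2, a carnitine palmitoyltransferase (−1.08 ± 0.10). For lipid droplets it was 0 and 4 of 21 (0 and 8 adjusted over the list alone; camera adjusted p = 0.000454, adjusted p = 0.322 with an estimated correlation). Complement genes were higher in 4 of 33 cases and lower in 0 (6 and 0 adjusted over the list alone; camera adjusted p = 0.00556, adjusted p = 0.798 with an estimated correlation). Among them were C2 (0.76 ± 0.10) and Pros1, protein S (0.58 ± 0.12). Cholangiocyte markers were higher in 5 of 13 cases and lower in 0 (8 and 0 adjusted over the list alone; camera adjusted p = 2.31e-05, adjusted p = 0.318 with an estimated correlation), beside the 60.8 CPM of Krt19 in KO female vehicle replicate 1. Krt19 differed by 3.67 ± 0.77 (adjusted p = 0.0167), and by 1.08 (adjusted p = 0.395) without that library. Arg1, the urea cycle arginase, was lower by a log2 difference of −0.74 ± 0.12.

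On PFOA the genotypes differed in more genes, 1127 higher and 1232 lower in KO, 6 libraries against 5. Plin5 was lower by a log2 difference of −4.0 ± 0.20 (adjusted p = 7.33e-11), Mogat1 by −4.94 ± 0.33 (30.7-fold, adjusted p = 7.35e-09) and Ehhadh by −2.86 ± 0.16 (7.28-fold, adjusted p = 7.33e-11). Cyp4a10 was lower by −3.57 ± 0.55 and Cyp4a14 by −5.28 ± 0.72 (38.9-fold, adjusted p = 0.000189). S100a8 was 31.1-fold higher in KO (4.96 ± 0.37, adjusted p = 3.36e-07), Wif1 was higher by 3.99 ± 0.48 and Slc13a2, a citrate transporter, by 3.32 ± 0.29. Fasn (−1.40 ± 0.28, adjusted p = 0.00349), Srebf1, the lipogenic transcription factor (−1.53 ± 0.24), and Scd1, stearoyl-CoA desaturase (−2.14 ± 0.42), were lower. Ppara was lower by −0.71 ± 0.20 (adjusted p = 0.0203), a call lost without hPPARa female PFOA replicate 1 (−0.68, adjusted p = 0.0598), without hPPARa male PFOA replicate 3 (−0.61, adjusted p = 0.0559) and without the 3 KO libraries with transcripts of the other sex (−0.67, adjusted p = 0.0844).

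On PFOA 0 of 25 peroxisomal genes were higher and 24 lower in KO (0 and 24 adjusted over the list alone; median −1.68, camera adjusted p = 5.95e-35). It was 0 and 19 of 23 for mitochondrial oxidation (0 and 20 adjusted over the list alone; camera adjusted p = 2.03e-24) and 0 and 19 of 21 for lipid droplets (0 and 19 adjusted over the list alone; camera adjusted p = 2.61e-21). These 3 kept their call with an estimated correlation (adjusted p = 0.000922, 0.00159 and 0.00127). CAR and PXR targets were higher in 16 of 40 cases and lower in 1 (18 and 2 adjusted over the list alone; camera adjusted p = 2.33e-07, adjusted p = 0.0969 with an estimated correlation). Cyp2c55 stood at 2.07 ± 0.21 and Ces2a at 1.16 ± 0.15, and Cyp2b10 at 0.79 ± 0.31 (adjusted p = 0.103). Fatty acid synthesis genes were higher in 0 and lower in 10 of 26 cases (1 and 13 adjusted over the list alone; camera adjusted p = 7.06e-05, adjusted p = 0.229 with an estimated correlation). Acute-phase genes were higher in 10 of 28 cases and lower in 0 (11 and 0 adjusted over the list alone; camera adjusted p = 3.74e-07, adjusted p = 0.103 with an estimated correlation). Orm2 stood at 1.48 ± 0.20, and interferon genes in 10 of 24 and 0 (15 and 0 adjusted over the list alone; camera adjusted p = 1.37e-08, adjusted p = 0.265 with an estimated correlation). Ifit1 stood at 2.22 ± 0.40. Unfolded protein and integrated stress genes were higher in 8 of 25 cases and lower in 1 (15 and 1 adjusted over the list alone; camera adjusted p = 6.84e-06, adjusted p = 0.0541 with an estimated correlation). Ddit3 stood at 1.22 ± 0.22. Kupffer cell markers were higher in 11 of 20 cases and lower in 0 (15 and 0 adjusted over the list alone; camera adjusted p = 3.81e-06, adjusted p = 0.229 with an estimated correlation). C1qb stood at 0.85 ± 0.17, and endothelial markers higher in 0 and lower in 7 of 17 (0 and 12 adjusted over the list alone; camera adjusted p = 3.61e-05, adjusted p = 0.265 with an estimated correlation). Stab1 stood at −0.60 ± 0.13. Cell cycle genes were higher in 0 and lower in 7 of 32 cases (0 and 9 adjusted over the list alone; camera adjusted p = 6.84e-06, adjusted p = 0.265 with an estimated correlation). Cdk1 stood at −1.36 ± 0.23.

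Sex differences, male minus female with exposure as a term, were tested in each genotype. In hPPARa livers 221 genes were higher and 280 lower in males. The major urinary protein genes Mup21 and Mup20 were higher in males by 6.34 ± 0.54 (adjusted p = 0.000837) and 3.94 ± 0.48. Cyp2c40 (−8.80 ± 0.71, adjusted p = 0.000486), Cyp3a44 (−7.15 ± 0.83, −7.74 with DESeq2), A1bg (−6.86 ± 0.50, adjusted p = 4.42e-05) and Xist (−8.15 ± 0.72, adjusted p = 0.00113) were higher in females. Mup, Cyp2c and Cyp3a members could have shared reads with close copies in the counting. Male-biased liver genes were higher in 14 of 29 cases and lower in 0 (24 and 0 adjusted over the list alone; camera adjusted p = 2.35e-27, adjusted p = 0.0689 with an estimated correlation). Female-biased genes were lower in 11 of 31 and higher in 0 (1 and 21 adjusted over the list alone; camera adjusted p = 8.72e-25, adjusted p = 0.0804 with an estimated correlation). Kupffer cell markers were lower in males in 11 of 19 cases and higher in 0 (0 and 15 adjusted over the list alone; camera adjusted p = 4.22e-14, adjusted p = 0.0804 with an estimated correlation). Among them were C1qa (−1.08 ± 0.12) and Clec4f (−0.96 ± 0.13), a Kupffer cell lectin. Cell cycle genes were lower in 7 of 32 cases and higher in 0 (0 and 18 adjusted over the list alone; camera adjusted p = 4.16e-11, adjusted p = 0.245 with an estimated correlation). Among them were Ccnd1, cyclin D1 (−2.19 ± 0.24), and Top2a (−1.16 ± 0.20). Cyp39a1, an oxysterol hydroxylase, was lower in males (−2.21 ± 0.28) and Scp2, a sterol carrier, higher (0.98 ± 0.13). The sum of 501 calls became 282 without hPPARa male vehicle replicate 1, 315 without hPPARa male PFOA replicate 2, 306 without hPPARa female PFOA replicate 1 and 255 without hPPARa female PFOA replicate 2.

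In KO livers 193 genes were higher and 330 lower in males. Clec2h was higher in males by 4.63 ± 0.49 (adjusted p = 0.000309) and Mup21 by 4.51 ± 0.49 (5.27 without the 3 KO libraries with transcripts of the other sex). Cyp17a1, the steroid 17-hydroxylase (−4.61 ± 0.35), Abcd2, a peroxisomal fatty acid transporter (−3.35 ± 0.29, adjusted p = 0.000107), Nipal1 (−3.03 ± 0.18, adjusted p = 2.39e-06) and Cyp39a1 (−3.07 ± 0.21, adjusted p = 2.75e-05) were lower. Scp2 was higher by 1.14 ± 0.10 and Tm6sf2, a regulator of lipoprotein secretion, lower (−1.45 ± 0.12). Male-biased genes were higher in 16 of 30 cases and lower in 0 (26 and 0 adjusted over the list alone; camera adjusted p = 2.03e-25, adjusted p = 0.112 with an estimated correlation). Female-biased genes were lower in 20 of 31 and higher in 0 (0 and 26 adjusted over the list alone; camera adjusted p = 6.86e-25, adjusted p = 0.112 with an estimated correlation). Lymphocyte markers were lower in 3 of 20 cases and higher in 0 (0 and 15 adjusted over the list alone; camera adjusted p = 3.54e-09, adjusted p = 0.123 with an estimated correlation). The Y-linked gene Uty differed by 4.88 ± 0.63, which became 6.05 without KO female PFOA replicate 2 and 10.98 without the 3 KO libraries with transcripts of the other sex. The sum of 523 calls became 127 without KO female vehicle replicate 1, of which 68 were higher and 59 lower, and 334 without KO male vehicle replicate 1. It became 94, of which 52 were higher and 42 lower, without the 3 KO libraries with transcripts of the other sex.

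The sex by genotype term called 0 of 15811 genes by edgeR's quasi-likelihood test, with 972 at an unadjusted p under 0.05, 15 called by DESeq2 and 82 called without the filter on low counts. The 5 smallest unadjusted p belonged to Prr15l (−3.27 ± 0.59, adjusted p = 0.264), Alg8, a glucosyltransferase (0.70 ± 0.14, adjusted p = 0.267), Chrna2 (2.13 ± 0.42, adjusted p = 0.267), Slc9a3, a sodium-proton exchanger (−10.87 ± 2.03, adjusted p = 0.338), and Rapgefl1 (−1.62 ± 0.35, adjusted p = 0.411), none of them past the threshold by this test. With DESeq2 Prr15l (adjusted p = 0.0114), Alg8 (0.0114), Chrna2 (0.000681) and Rapgefl1 (0.0178) passed. Without the filter on low counts Prr15l (adjusted p = 3.7e-05), Chrna2 (1.14e-09), Slc9a3 (3.54e-13) and Rapgefl1 (0.000234) passed. Slc9a3 had 25.3 CPM in KO female vehicle replicate 1 and at most 0.47 CPM in any other library, so its value rests on that library. Prr15l was at 7.19 CPM there, against means of 0.17 to 0.804 CPM in the other groups. Chrna2 passed as well without KO female PFOA replicate 2 (2.59, adjusted p = 0.0339). Of the genes called in either genotype, 75 were higher in males in both, of 220 and 181, against 2.80 for independent lists, and 80 were lower in both, of 278 and 283, against 5.53, with 155 of 155 of the same sign.

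A score per library, the mean log2 CPM of the male-biased genes minus that of the female-biased genes, summarised both lists. Members with a very low mean CPM over all libraries were left out of it. The female-biased list shares Cyp2b9, Cyp2b13, Cyp3a16, Cyp3a41a and Cyp3a44 with the CAR and PXR list and Acot3 with the peroxisomal list. Both of those lists rose with PFOA, and the score was not computed without the shared genes. In males it was 5.10 ± 0.53 (SD, n = 2) on vehicle and 3.44 ± 0.64 (n = 3) on PFOA in hPPARa, and 5.81 ± 0.62 (n = 3) and 4.53 ± 0.50 (n = 3) in KO. In females it was −2.85 ± 0.57 (n = 3) on vehicle and −0.85 ± 0.59 (n = 2) on PFOA in hPPARa, and −2.33 in the 1 KO library on vehicle and −0.09 ± 1.13 (n = 3) on PFOA. The difference with PFOA was −1.66 in hPPARa males and −1.28 in KO males, with a two-sided exact permutation p of 0.01 over 200 arrangements within genotype. It was 2.0 in hPPARa females and 2.24 in KO females, with a two-sided exact permutation p of 0.025, the smallest that 40 arrangements allow. KO female PFOA replicate 2, with 4.07 CPM of Ddx3y, had the highest female score, 0.91, and without it the difference in KO females is 1.74 and the exact p 0.0667. KO male PFOA replicate 2, with 30.8 CPM of Xist, had the lowest score of the KO males, 3.98, and without it the difference is −1.01 and the exact p 0.02. KO female vehicle replicate 1 is the 1 female KO library on vehicle, so the KO difference in females cannot be had without it. In the KO libraries alone the exact permutation p was 0.1 in males and 0.25 in females, the smallest that 20 and 4 arrangements allow. The hPPARa libraries alone were not tested, and the permutation p of 0.01 and 0.025 joined both genotypes. These tests therefore do not show whether the score changed in both genotypes or in 1 of them.

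**Figure D3:**
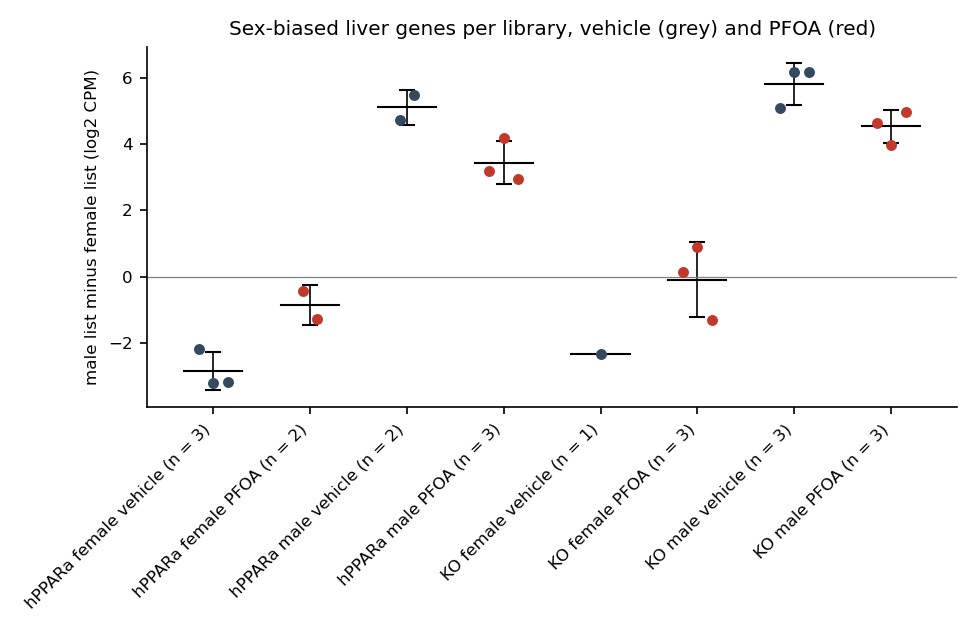
Mean log2 CPM of the male-biased minus the female-biased liver genes; a point is a library, a line the group mean and a bar its SD, absent for the 1 KO female on vehicle. Female groups moved up and male groups down with PFOA, from −2.85 to −0.85 in hPPARa females and from 5.10 to 3.44 in hPPARa males.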

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

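The counts over other splits of the libraries were planned, and the tests of mixed RNA, paralogs, the Ppara values, cell type lists in 1 library and the sex score were chosen only after the results were seen. The PFOA response differed between the genotypes, by the interaction test of the difference itself, in 185 genes (70 higher and 115 lower; 23 and 16 without the 3 KO libraries with transcripts of the other sex). The 8 with the smallest adjusted p were Hsd17b11 (log2 difference, KO minus hPPARa, −1.78), Ehhadh (−2.52), Chrna2 (−3.26), Bhlhb9 (−3.29), Acot8 (−0.92), Serinc2 (−6.22), Nrp2 (−1.62) and Acsf3 (−0.70), all lower in KO livers. Serinc2 stood at −4.65 without KO female vehicle replicate 1 and at −4.38 without the 3 KO libraries with transcripts of the other sex, a setting in which Nrp2 lost its call (−1.37, adjusted p = 0.089 by edgeR's quasi-likelihood test).

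The PFOA response differed between hPPARa males and females, by the interaction test, in 15 genes (6 higher and 9 lower in males; 79 and 59 with DESeq2), led by Cyp2c67 (log2 difference, male minus female, −2.18), Cyp2c29 (−2.47), Alas2 (−2.35), F2r (−1.40), Arsa (−2.12), Cyp4a12a (−7.52), Evc (−1.79) and mt-Te (1.94). The last 5 lost their call, by edgeR's quasi-likelihood test, without 1 or more single hPPARa libraries. With the replicate number as a block Alas2 (−2.30, adjusted p = 0.0515), Cyp4a12a (−7.7, 0.1) and Evc (−1.65, 0.0654) lost theirs by the same test. Without male vehicle replicate 2, F2r stood at −1.25 (adjusted p = 0.103), Arsa at −2.05 (0.103), Cyp4a12a at −7.57 (0.0693), Evc at −1.79 (0.103) and mt-Te at 1.88 (0.137). Without female PFOA replicate 1 they stood at −1.40 (0.0944), −1.90 (0.0944), −7.22 (0.0944), −1.90 (0.0885) and 1.84 (0.149). Without female PFOA replicate 2, F2r (−1.42, 0.0953), Cyp4a12a (−7.76, 0.0953), Evc (−1.67, 0.125) and mt-Te (2.05, 0.1) missed the threshold. Without male vehicle replicate 1 these were Arsa (−2.19, 0.0503), Cyp4a12a (−7.46, 0.0537), Evc (−1.79, 0.0743) and mt-Te (2.02, 0.0743), and without female vehicle replicate 1 Arsa (−2.17, 0.0556), Cyp4a12a (−7.45, 0.0649) and mt-Te (1.89, 0.0521). Cyp4a12a also missed it without male PFOA replicate 1 (−7.58, 0.0516) or replicate 3 (−7.43, 0.0502), and stood at −8.55 without female vehicle replicate 3.

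Other splits of the libraries into groups of the same sizes asked whether chance can be excluded. For PFOA in hPPARa 1 of 100 splits, the real one, reached its 3253 calls and the highest other gave 4, and for PFOA in KO 1 of 80 reached 2113 and the highest other gave 85. For the genotypes on vehicle 1 of 40 reached 596 (highest other 12) and on PFOA 1 of 100, drawn from 200, reached 2359 (highest other 119). For sex in hPPARa 1 of 100 reached 501 (highest other 7), and in KO 1 of 80 reached 523 (highest other 16). Among these samples chance is unlikely for these 6, by shares not adjusted over the comparisons. For the genotypes on PFOA the exact 95% interval from the draw was 0% to 3.66%. The labels do not say that samples are separate mice, so chance between mice is not excluded. For PFOA by genotype 4 of 100 splits, drawn from 8000, reached 185. This share is under 0.05, but its exact 95% interval from the draw, 0.629% to 8.6%, reaches past that. Genotype labels were swapped within sex and exposure, so genotype differences themselves can enter a split's count. The share therefore does not decide about chance, which is not excluded. The highest other split gave 784; it left the genotype labels of the PFOA libraries in place and changed 2 of 4 female and 4 of 5 male vehicle labels, so the difference between the genotypes on PFOA itself enters that count. In KO males the 10 splits are too few for a share under 0.05; the real split gave 1395 and the highest other 0. For sex by genotype the real split gave 0 calls, which all 100 splits reach by necessity, so the count decides nothing about chance; the highest other gave 180, with the female labels in place and 4 of 6 male PFOA and 4 of 5 male vehicle labels changed, so the genotype difference enters it too.

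The first pattern is the rise of 19 of 25 peroxisomal and PPARα-inducible genes with PFOA in livers labelled as lacking PPARα. RNA of hPPARa PFOA livers mixed into the 6 KO PFOA libraries would bring all transcripts in 1 share, which Cyp4a14 limits to 0.778% to 8.11%; the criterion set at first, over 1.5 times that share in each library for most of the 19, was missed with 8, and the test was then divided and its bound set anew from the extreme libraries. By that bound mixing is argued against as the whole cause for 15 members that need more than Cyp4a14 allows in at least 4 of the 6 libraries, such as Acaa1b and Eci2 in 6, Cyp4a10 in 6 and Ehhadh in 5, while for the other 4, Cyp4a14, Cyp4a31, Cyp4a32 and Vnn1, it cannot be told apart from a response of the liver, since a share up to 8.11% is allowed. Reads shared between paralogs are argued against as the whole cause, because 11 of 15 members outside the Cyp4a, Acaa1 and Acot1 to Acot4 families rose and 0 fell. A candidate explanation, that PFOA acts on these genes without PPARα, cannot be told apart from action through a remaining receptor, since the deleted part of the gene is not given. Mean Ppara CPM in KO libraries was 73.6% of that in hPPARa libraries. Whether this row counts the human receptor is not known, so 73.6% is not a share of receptor. On vehicle the peroxisomal list was lower in KO than in hPPARa livers, which does not tell a lost receptor from a weaker one.

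The second pattern is the epithelial transcripts in KO female vehicle replicate 1, with 849 CPM of Dmbt1, 103 of Spp1, 60.8 of Krt19, 25.3 of Slc9a3 and 13.2 of Muc3. Bile duct or gallbladder tissue in this sample may account for them. Of the 13 cholangiocyte markers 11 had a count in each of the 3 KO male vehicle libraries, so liver also expresses some. Over those libraries the 13 had a median log2 ratio of 1.06, at percentile 99.99 of 10000 random lists matched on expression. This list holds Krt19 and Spp1, and its median is the value of Spp1, so it is not independent of the pattern. A lower share of hepatocytes, which would raise every other cell type alike, is not excluded. These 5 transcripts had a median log2 ratio of 6.45, against 3.08 for the highest of 59 Kupffer cell, stellate cell and endothelial markers. They were picked after their values were seen, so this comparison cannot decide it. The cholangiocyte list, fixed beforehand, had quartiles of 0.36 and 2.81. Medians were 0.61, 0.42 and 0.37 for the Kupffer cell, stellate cell and endothelial markers and −0.03 for the hepatocyte markers. The 3 KO female PFOA libraries had at most 0.0533 CPM of Dmbt1, 0.604 of Krt19 and 41.1 of Spp1, and 0 of Slc9a3 and Muc3. These values argue against sex and genotype as the whole cause whatever the exposure. For KO females on vehicle, sex and genotype cannot be told apart from a feature of the sample, because there was 1 such library. The highest KO male vehicle library had 27.9 CPM of Dmbt1.

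The third pattern is the narrower sex-biased expression with PFOA in hPPARa livers. RNA of the other sex is argued against in the females, where the 4 Y-linked genes reached at most 0.0867% of the male level while the 6 male-biased genes called higher reached a median of 19.8%. It is argued against in the males too, where Xist reached at most 0.621% of the female level against a median of 44.3% for the 5 female-biased genes called higher. Of these genes Cyp2b9 and Cyp2b13 also stand in the CAR and PXR list, which rose with PFOA. Cyp4a12b in females reached 312% of the male level and Rarres1 in males 1060% of the female level, so both passed the other sex. Whether PFOA induced such genes apart from their sex bias was not tested. A change that both genotypes share cannot be told apart from one in a single genotype. In the KO males alone the two-sided exact permutation p of the sex score was 0.1, the smallest that 20 arrangements allow. The hPPARa libraries alone were not tested. The score differences with PFOA went the same way in hPPARa and KO, −1.66 and −1.28 in males and 2.0 and 2.24 in females. KO male PFOA replicate 2 and KO female PFOA replicate 2 also held transcripts of the other sex, and mixing was not tested in the KO libraries. Hormones and growth hormone pulses, which set these genes in liver, were not analysed here.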

How the results depend on the processing

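Among the settings, leaving out the 3 KO libraries with transcripts of the other sex was chosen after seeing the data. For the named genes 3045 values were computed under alternatives, of which 2979 kept their direction and side of the threshold, 50 lost their call, 16 gained one and 0 reversed. These genes were narrowed to those whose call held, so the numbers do not measure how stable the calls are. Of all calls, DESeq2 shared 97.7% for PFOA in hPPARa, 96.2% in KO and 98.9% for PFOA by genotype. Counts of calls moved more. With DESeq2 there were 138 genes for PFOA by sex, 423 for PFOA by genotype, 920 for the genotypes on vehicle, 927 for sex in hPPARa, 930 for sex in KO and 15 for sex by genotype, and the cause was not tested. Without the filter on low counts, so with more genes tested, they were 323, 545, 1013, 1088, 1322 and 82, and 1490 for PFOA in KO females. The joint fit gave 836 for sex in KO, and the cause was not tested. Without the 3 KO libraries, so with fewer samples, PFOA in KO gave 630, PFOA by genotype 39, sex in KO 94 and sex by genotype 2. No list test was repeated with libraries left out. Lists past the threshold numbered 3 of 14 with an estimated correlation for PFOA in hPPARa, 3 of 12 in KO, 4 of 14 for PFOA by genotype, 1 of 7 for the genotypes on vehicle, 3 of 14 on PFOA, 0 of 10 for sex in hPPARa, 0 of 14 in KO and 0 of 7 for sex by genotype, where the alternative itself widens the test. At an unadjusted p the genotypes shared 1251 higher and 987 lower genes with PFOA, by a looser threshold, and with a log2 fold change of at least 1 they shared 40 genes lower in males, by a stricter one.

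Leaving out 1 library at a time gave 1905 to 3889 calls for PFOA in hPPARa, 468 to 1162 in its males, 796 to 2461 in its females and 4 to 27 for PFOA by sex. It gave 1401 to 2129 for PFOA in KO, 635 to 1090 in its males and 608 to 676 in its females, whose 1 vehicle library cannot be left out. For PFOA by genotype it gave 67 to 239, for the genotypes 351 to 511 on vehicle and 1638 to 2223 on PFOA, for sex 255 to 686 in hPPARa and 127 to 609 in KO, and 0 to 1 for sex by genotype. A group left with 1 library was assumed to vary like the others.

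The replicate numbers were not taken to pair the samples, since the correlations were not above 0.1 in every pair. Deviations from the group means correlated at −0.129 to 0.343 (median 0.0186) over 52 pairs with the same number, 6 of them above 0.1, against a median of −0.0104 over 102 other pairs, and 5 of 19 libraries correlated best with their own number within their genotype, but 11 of 19 over all groups, against 6.41 by the numbers alone. Exceptions above 0.1 were the 3 pairs of hPPARa male PFOA with KO female PFOA (0.131, 0.238 and 0.343), both pairs of hPPARa with KO male vehicle (0.142 and 0.197) and 1 pair of hPPARa female with male vehicle (0.103), so a shared factor in those groups stays open. With the replicate number as a block, PFOA in KO females gave 396 calls and sex in KO 206, with fewer degrees of freedom. With this block Krt19 with PFOA in KO (adjusted p = 0.0814 by edgeR's quasi-likelihood test), and Alas2 (0.0515), Cyp4a12a (0.1) and Evc (0.0654) for PFOA by sex, did not pass, and Sult2a1 with PFOA in KO stood at −8.43. mt-Te missed the threshold in the joint fit (0.491).

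In simulated counts the tests within 1 sex recovered 7.25%, 41.2% and 79.4% of changes of 1.5, 2 and 4-fold in hPPARa males, 10.3%, 54.2% and 84.3% in hPPARa females, 21.1%, 61.8% and 82.4% in KO males and 0%, 15.6% and 69.2% in KO females. For sex by genotype these were 11.5%, 46.2% and 61.4%, so a smaller difference there was mostly not detectable at this depth and number of libraries.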

Other observations

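The genes in this part were chosen after their values were seen. Pnliprp1, a pancreatic lipase-related protein, rose with PFOA in hPPARa livers by 5.94 ± 0.41 on the log2 scale (adjusted p = 6.97e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In KO livers it had 345 counts on PFOA against 2 on vehicle, a ratio of 105 with an exact 95% interval of 28.9 to 873 for counting error only. S100a8 rose in hPPARa livers by 4.60 ± 0.41 (adjusted p = 8.35e-06), from 0.122 to 0.277 CPM in the vehicle libraries to 2.85 to 8.49 CPM in the PFOA libraries, and in KO livers from 0.252 to 0.541 CPM to 87.9 to 325 CPM. Its usual partner in calprotectin, S100a9, had log2 fold changes of 0.65 ± 0.43 (adjusted p = 0.294) in hPPARa and 0.30 ± 0.51 (adjusted p = 0.746) in KO. The difference of the S100a8 responses, KO minus hPPARa, was 4.25 ± 1.30 (adjusted p = 0.14), not past the threshold, though it passed without KO male PFOA replicate 1 (4.55, adjusted p = 0.0253) and with DESeq2 (4.18, adjusted p = 9.89e-06).

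Rpl29, a ribosomal protein gene, and Acpp, an acid phosphatase gene, differed within the hPPARa groups. In 7 of the 10 hPPARa libraries Rpl29 lay at 6.31 to 9.20 CPM and Acpp at 1.64 to 5.33 CPM. In hPPARa female PFOA replicate 2 they were at 1.88 and 0.341 CPM, in male PFOA replicate 2 at 0.93 and 0, and in male PFOA replicate 3 at 0.964 and 0. These low libraries were all on PFOA, and every hPPARa vehicle library was among the 7. The split is thus unbalanced over exposure, and whether it bears on the PFOA comparison in hPPARa livers was not tested. In the KO libraries Rpl29 lay at 0.155 to 1.08 CPM. On vehicle the log2 difference, KO minus hPPARa, was −4.01 for Rpl29 (adjusted p = 0.0109 by edgeR's quasi-likelihood test), which became −3.47 (adjusted p = 0.0686) without KO female vehicle replicate 1 and −4.69 without KO male vehicle replicate 2. For Acpp it was −5.47 (adjusted p = 0.0216), which became −4.68 (adjusted p = 0.267) without KO female vehicle replicate 1 and −6.74 without KO male vehicle replicate 1.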
